A study of Mus musculus with 2 samples.

How the data were processed

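RNA of single brain cells was measured in 2 libraries, 1 from pooled mice on control diet (CD) and 1 from pooled mice 5 days after PLX5622 (Repop D5). Per the labels, tissue was dissociated with papain at body temperature, myelin was removed on a Percoll gradient, dead cells were excluded by dye, and CD11b+/CD45+ cells were sorted before 10x Genomics library preparation and sequencing on an Illumina instrument. Per the submitters' processing notes, reads were mapped to mm10 and counted with Cell Ranger 2.1.0, and the annotation release and the rule for calling cells are not stated. The deposited matrices hold raw UMI counts per gene and cell barcode, as whole numbers over 27998 genes, checked against the size line of each file. The authors also made a pooled matrix of counts of both libraries. In it the CD counts were identical to the CD library's own matrix, and the Repop D5 counts came to 96.8% of the UMIs in the Repop D5 matrix, with 236078 entries lower and 0 higher. The library matrices were used here and the pooled matrix served as an alternative. Its cells were assigned by the barcode lists, which share 1 barcode.

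Cells with at least 500 genes and under 10% of UMIs from mt- genes were retained, 609 of 609 in CD and 553 of 585 in Repop D5. No doublets were removed in the main values. The cells of both libraries were clustered together with scanpy 1.11.5 in Python 3.11.15 (log counts per 10000, 2000 variable genes, 30 principal components, 15 neighbours, Leiden at resolution 1 with leidenalg 0.10.2, fixed seed), which gave 12 clusters. No correction between libraries was applied, since library and group are the same. Markers of 19 cell types were fixed before the data were examined, as were the cell filter, the gene lists, the rules for naming genes and the alternatives, apart from those described here as chosen later. How markers turn into a name was set after the clusters were seen. The 10 leading genes of a cluster are those with the highest fold over all other cells among genes at 50 CPM and found in at least 25% of its cells. A cluster with 3 or more leading genes from another class's markers takes that name, and one with 2 stays unnamed. Other clusters are microglia-like if at least 3 microglia markers reach 50 CPM in them. Leading genes with no detection minimum and with 20% were also looked at. The class passed for comparison only if no cluster of it had more markers of another class than of microglia among its leading genes. Clusters 1 and 2 failed this.

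UMIs were summed over every retained cell of a library, the fallback planned for that case, and scaled to the same total in both libraries (CPM). The depth was 6055886 UMIs in CD and 11037921 UMIs in the retained Repop D5 cells, so a floor of 3 counts is under 1 CPM in each. The ratio of a gene is its Repop D5 CPM over its CD CPM with the exact conditional binomial 95% interval for 2 Poisson counts. Genes with at least 50 CPM in 1 of the libraries and a ratio of 2 or more, or its inverse, with an interval clear of 1, were counted as higher or lower. For each of 26 gene lists, members with at least 10 CPM in 1 library were measured, and 2 listed genes were not in the gene files. A member was called higher or lower at a ratio of 1.5 or its inverse with an interval clear of 1. The list value is the median of log2((CPM + 1) in Repop D5 over (CPM + 1) in CD), with a 95% interval from 1000 Poisson redraws. Its percentile is among 10000 random lists of the same size matched on mean expression in 20 bins. Shares of cells have exact Clopper-Pearson intervals, except that a share of 0 is given the limit of 3 counts of the total. Shares of cells with a UMI were taken after thinning every cell to 3000 UMIs, the largest multiple of 500 that 90% of the cells of each library reach, as the median of 20 seeded draws. Shallower cells were left out.

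The genes named are the 15 with the highest and the 15 with the lowest ratios among genes at 50 CPM with an interval clear of 1, leaving out predicted, ribosomal protein, mt-, haemoglobin and sex-linked genes. A gene with 0 counts in 1 library was ranked with 0.5 counts added to both. In each list, examples come from the 2 highest, the 2 lowest and the 2 most abundant measured members. Csf1r, Nes, Mki67, P2ry12, Tmem119, Cx3cr1, Lgals3 and Ccr2 are always named. The same rule was applied to cells outside clusters 4, 6 and 9. Coordinates are from GENCODE M21, and 43 of 43 gene identifiers were found in it.

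The alternatives fixed in advance were no cell filter, a stricter one (1000 genes and 5% mt-), a trimmed-mean scaling, totals without mt- and ribosomal protein genes, equal weight per cell, thinned cells, the pooled matrix, and removal of doublets called by Scrublet (expected share 5%) or of the 5% of cells with the most UMIs. Others were gene minimums of 10 CPM and none, list minimums of 50 CPM and none, a pseudocount of 10 CPM, Leiden at resolutions 0.5 and 2, 15 principal components, and other measures of Mki67. Summing the cells outside clusters 4, 6 and 9 was added after the data were seen. The calculation was tested on simulated Poisson counts at the depths of these libraries. No spread between cells, mice or preparations was simulated, so this checks the calculation and gives no error rate for these data. Of ratio intervals, 95.2% held the true ratio, 0 of 50 genes set to a 1.5-fold difference, 26 of 50 set to 2-fold and 49 of 50 set to 3-fold were counted at the 2-fold rule, and 0 genes with no difference were. Left out were the 32 Repop D5 barcodes above the mt- limit, and genes below the minimums. Numerical work used numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.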

Results

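The data are droplet single-cell RNA counts (10x Genomics) of brain cells sorted by flow cytometry as CD11b+/CD45+ from adult C57BL/6J mice, both surface proteins being carried by microglia and by other myeloid cells. Each group is 1 library. The CD library pooled 4 mice fed control diet for 19 days, and the Repop D5 library pooled 6 mice that received PLX5622, an inhibitor of the receptor Csf1r on which microglia depend, for 14 days and then control diet for 5 days. The labels state 609 and 585 cells, and the matrices held 609 and 585 barcodes. The CD library had 6055886 UMIs (unique molecular identifiers, each standing for 1 captured RNA molecule), with a median of 5982 UMIs and 2147 genes per barcode. The Repop D5 library had 11300334 UMIs, with a median of 15772 UMIs and 3598 genes per barcode, so its median UMI count was 2.64 times that of CD, while the reads per cell stated in the labels differed by a factor of 1.04. The median share of UMIs from mt- genes, the genes of the mitochondrial genome, was 2.00% in CD and 4.88% in Repop D5. The cell filter left 609 CD and 553 Repop D5 cells, the latter with a median of 16226 UMIs. With 1 library per group there is no test between groups and no estimate of the spread between mice. Every 95% interval given here covers counting error only, and "higher" and "lower" describe the Repop D5 library relative to the CD library.

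The first question is which cells the sort delivered in each library. The clusters other than 4, 6 and 9, named microglia-like, held 430 of 609 CD cells (70.6%, exact 95% interval 66.8 to 74.2). They held 502 of 553 Repop D5 cells (90.8%, 88.1 to 93.1). This class failed the check for comparison described with its clusters, so its shares are given per library and not compared. Cluster 4, border macrophage-like and led by Lyve1, Cd209f, Cd163 and Mrc1, known from macrophages at the vessels and coverings of the brain, held 108 CD cells (17.7%, 14.8 to 21.0). It held 0 of 553 Repop D5 cells, which allows a share of up to 0.542%. Both shares of cluster 4 are those of the main clustering and were not taken under the alternatives. Cluster 6, monocyte-like and led by Plac8, Ccr2, Ly6c2 and MHC class II genes and with endothelial markers at 605 CPM (the count of a gene scaled to 1 common total of UMIs per library), held 4.76% of CD cells (3.21 to 6.77) and 7.96% of Repop D5 cells (5.84 to 10.5). Cluster 9, neutrophil-like and led by Ngp, Camp, S100a8 and S100a9, held 6.90% of CD cells (5.02 to 9.21) and 1.27% of Repop D5 cells (0.510 to 2.59). The sort gate, the density gradient and the number of mice per pool can all set such shares. The border macrophage-like CD barcodes also carried microglial RNA, with the microglia markers at 23600 CPM, and had a median of 17119 UMIs against 5026 in the CD microglia-like clusters.

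**Figure D1:**
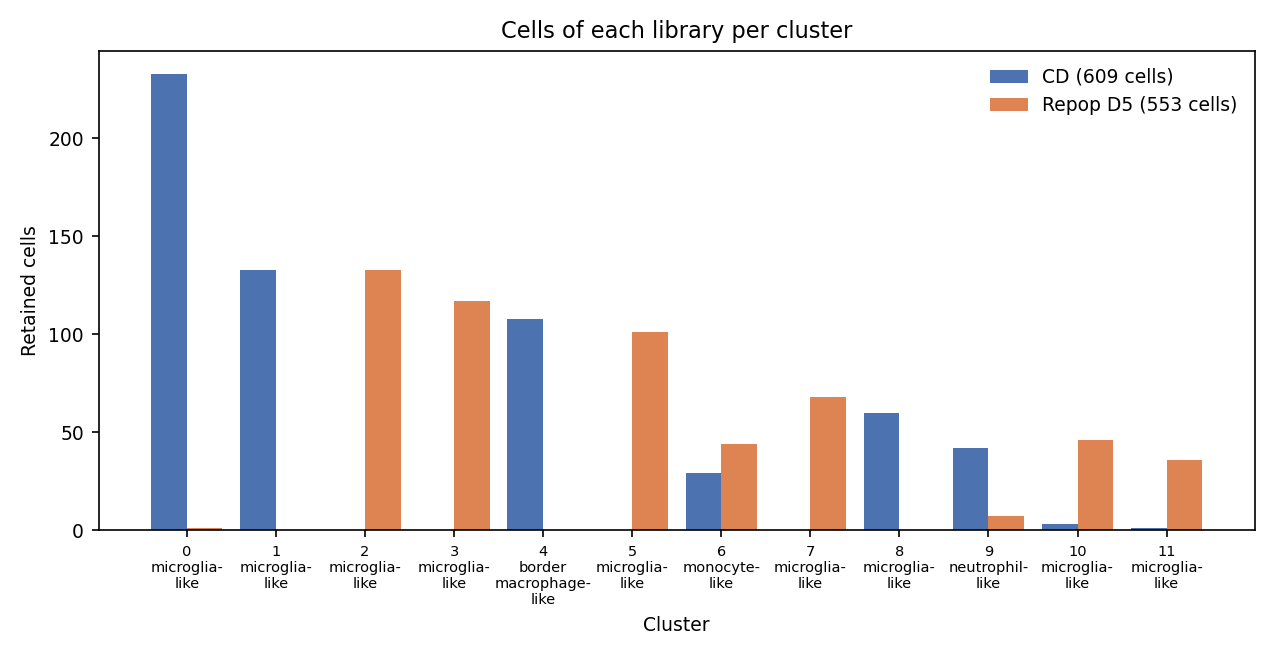
Retained cells of each library (vertical axis, number of cells) in each of 12 clusters found over both libraries together (horizontal axis, with the name each received from fixed markers), as bars for CD (609 cells) and Repop D5 (553 cells). Cluster 4, border macrophage-like, holds 108 CD cells and 0 Repop D5 cells, and the microglia-like clusters hold cells almost wholly of 1 library each.

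The CD microglia-like cells lay in clusters 0, 1 and 8 and those of Repop D5 in clusters 2, 3, 5, 7, 10 and 11, except for 4 CD cells and 1 Repop D5 cell. A cluster of 1 library may be that library and not a type, so sizes of these clusters are not compared. Clusters 1 and 2 each had a marker of another class (Slc1a3 of astrocytes, Nes of neural progenitors) and none of microglia among their 10 leading genes. No other cluster had a microglia marker there either, since leading genes are ranked by fold over all other cells. Microglia markers at 50 CPM numbered 10 in cluster 1 and 9 in cluster 2, and 10, 9 and 10 in clusters 4, 6 and 9. The check thus does not show that clusters 1 and 2 lack microglial RNA, but 1 marker of another class was enough to fail it. The microglia-like class therefore did not pass the check set for comparing it between libraries, and the planned fallback was used: the UMIs of every retained cell were summed per library. Values from the cells outside clusters 4, 6 and 9 (430 CD and 502 Repop D5 cells) are given for named genes and lists whose ratio moved by over 1.5 times or turned, and for some others. That set of cells was chosen after the clusters were seen.

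The main comparison asks how the sorted cells 5 days after the end of depletion differ from those of untreated mice in gene expression. Genes of DNA synthesis and cell division were higher in Repop D5, and 8 of the 15 genes with the highest ratios are on the S phase or G2 and M phase lists. Homeostatic microglia genes, those of resting adult microglia, were lower as a list, and 2 of the 15 genes with the lowest ratios are on it. Mki67, the common marker of proliferating cells (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361, mm10), had 1.49 CPM in CD and 122 CPM in Repop D5, a ratio of 81.9 (95% interval 43.0 to 179), and of 134 (45.8 to 652) outside clusters 4, 6 and 9. P2ry12, the purinergic receptor of ramified microglia (ENSMUSG00000036353, chromosome 3, 59216272 to 59262871), had 2988 CPM in CD and 495 CPM in Repop D5, 6.04-fold lower (5.86 to 6.22). Csf1r, the target of PLX5622 (ENSMUSG00000024621, chromosome 18, 61100598 to 61132149), had 3259 and 1382 CPM, 2.36-fold lower (2.31 to 2.41). Nes, which encodes the intermediate filament nestin of neural progenitors (ENSMUSG00000004891, chromosome 3, 87971078 to 87980451), had 3.14 and 68.5 CPM, a ratio of 21.8 (13.9 to 36.5), and of 37.5 (17.2 to 103) outside clusters 4, 6 and 9.

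Most of the 15 genes with the highest ratios have known roles in nucleotide supply or division. Rrm2, a subunit of ribonucleotide reductase, had 0 UMIs in CD and 83.7 CPM in Repop D5, which makes it at least 169-fold higher against a floor of 3 counts over the CD library, while its exact 95% interval starts at 137. Tk1, thymidine kinase, was 147-fold higher (50.1 to 714), on 3 CD counts. Ccna2 was 111-fold, Ccnb2 82.8-fold, Cdca3 68.7-fold and Top2a, the topoisomerase of dividing cells, 65.1-fold higher. Pbk, Ube2c, Birc5 and Knstrn, a set of mitotic genes, were 61.0-, 52.9-, 52.5- and 38.8-fold higher. The others were Spp1 (osteopontin, 53.7-fold, from 2.15 to 115 CPM), Ass1 (argininosuccinate synthase, 52.3-fold), Slc2a6 (a member of the glucose transporter family, 46.4-fold) and Htra3 (a serine protease, 38.5-fold). Outside clusters 4, 6 and 9, the 15 highest also took in Ch25h (cholesterol 25-hydroxylase, 120-fold), Plp2 (84.3-fold), Cyp4f18 (71.2-fold), Vim (vimentin, 62.5-fold) and Ccdc109b (49.6-fold). These ratios rest on few CD counts, 2 for Ch25h, 3 for Plp2, 23 for Vim and 6 for each of the others. The interval of Plp2 was 28.7 to 410. All of these ratios were smaller in every retained cell. In that set Plp2 had 10.1 CPM in CD and 80.6 CPM in Repop D5, Cyp4f18 11.2 and 135 CPM, and Ccdc109b 6.27 and 94.7 CPM. Slc2a6 had 1.26 and 127 CPM outside clusters 4, 6 and 9, where Ccnb2 was 52.6-fold and Cdca3 43.2-fold higher. Ass1, Rrm2 and Tk1 had 0 UMIs in the CD cells of that set and were at least 103-, 91.7- and 78.1-fold higher against a floor of 3 counts over those cells, with exact intervals from 83.6, 74.4 and 63.4.

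Of the 15 genes with the lowest ratios, Crybb1 and Adgrg1 are on the homeostatic microglia list. Crybb1, a crystallin gene expressed in mature microglia, had 603 CPM in CD and 11.6 CPM in Repop D5, 52.0-fold lower (43.6 to 62.5). Lag3, an inhibitory immune receptor, was 56.9-fold lower (44.1 to 74.6), and Adgrg1, an adhesion receptor of microglia, 29.4-fold lower (23.9 to 36.5). Slc1a3, a glutamate transporter gene best known from astrocytes, was 39.1-fold lower, from 167 to 4.26 CPM. Slc40a1, which encodes the iron exporter ferroportin, was 17.0-fold lower, and the chemokine gene Ccl24 was 23.8-fold lower, but 8.90-fold outside clusters 4, 6 and 9. The others were Csmd3 (98.7-fold), Tnfrsf17 (78.8-fold), Mlph (45.0-fold), Sult1a1 (36.4-fold), Serpine2 (23.9-fold), Ecscr (22.3-fold), Upk1b (21.7-fold), Whrn (21.7-fold) and Tgfa (18.4-fold). Outside clusters 4, 6 and 9, Mgll (17.2-fold lower) stood among the 15 lowest in the place of Ccl24.

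**Figure D2:**
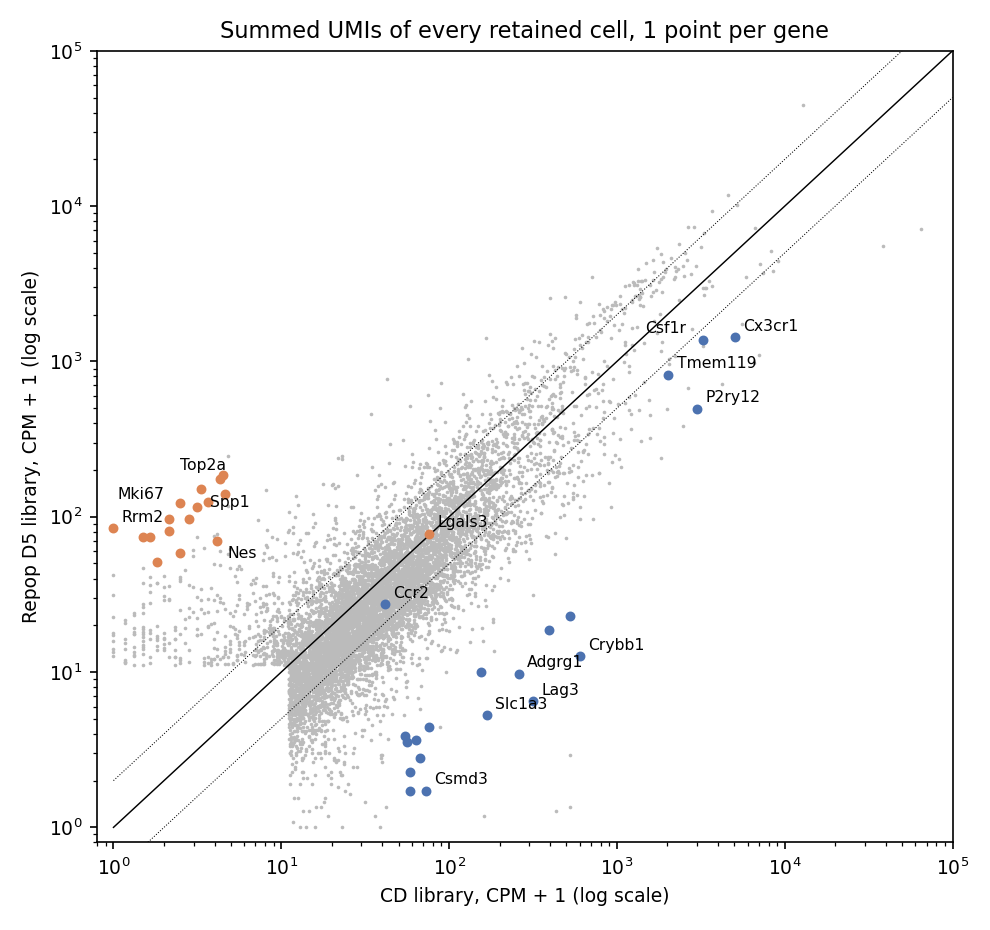
Each point is a gene with at least 10 CPM in 1 of the libraries, placed by its CPM + 1 in the CD library (horizontal, log scale) and in the Repop D5 library (vertical, log scale), summed over every retained cell, with lines at equal levels and at 2-fold. Orange and blue mark named genes with ratios above and below 1, such as Mki67 (1.49 and 122 CPM) and P2ry12 (2988 and 495 CPM), and Lgals3 lies on the line of equal levels.

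Of 3431 genes with at least 50 CPM in 1 of the libraries, 431 were at least 2-fold higher and 774 at least 2-fold lower with an interval clear of 1, a description by size and not a test. This split depends on the scaling. With a trimmed-mean scaling, which raises each gene's log2 ratio by 0.46, 981 were higher and 349 lower. With mt- and ribosomal protein genes left out of the totals, which raises it by 0.26, 701 were higher and 560 lower. The median log2 ratio of all genes at 50 CPM, a set that itself changes with the scaling, was -0.25 in the main values, 0.33 with the first of these and 0.026 with the second. The share of higher genes among both was 35.8%, 73.8% and 55.6% under the main scaling and these alternatives. The genes named so far keep their direction under each.

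The microglial identity genes were lower as a group. Of 25 homeostatic microglia genes, 22 were lower, 3 were neither and 0 higher, with a median log2 ratio of -1.82 (interval -1.85 to -1.79), below each of 10000 random lists matched on expression (percentile 0). Cst3, the gene of cystatin C and the most abundant in CD, had 64500 CPM in CD and 7140 CPM in Repop D5. Tmem119, a surface protein of microglia, was 2.46-fold lower (2.39 to 2.52), and Cx3cr1, the fractalkine receptor, 3.54-fold lower (3.47 to 3.61). Gpr165 had 13.7 and 0.272 CPM. Olfml3 (1653 and 1810 CPM, with the order turned outside clusters 4, 6 and 9) and Bin1 (681 and 613 CPM, with the order turned by the trimmed-mean scaling and without mt- and ribosomal protein genes) were the members nearest to equal levels. The median share of a cell's UMIs from this list was 11.3% in CD and 2.41% in Repop D5. The members summed to 105685 CPM in CD and 24502 CPM in Repop D5, of which Cst3 alone made 64500 and 7140 CPM. This share thus leans on 1 gene, which the median log2 ratio weighs as 1 of 25. P2ry12 had a UMI in 97.2% of CD cells (95.5 to 98.3) and 70.2% of Repop D5 cells (66.2 to 74.0) after thinning to 3000 UMIs, and in 98.7% and 95.7% before it. In neutrophil-like cells, which should lack the gene, the thinned share was 82.9% in CD (34 of 41 cells, median 6387 UMIs) and 42.9% in Repop D5 (3 of 7 cells, median 5416 UMIs), but these barcodes are not a clean background. The CD barcodes of cluster 9 together held the microglia markers at 18478 CPM. The level was 3707 CPM in the 10 of them richest in neutrophil markers, but those were picked by their composition.

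**Figure D3:**
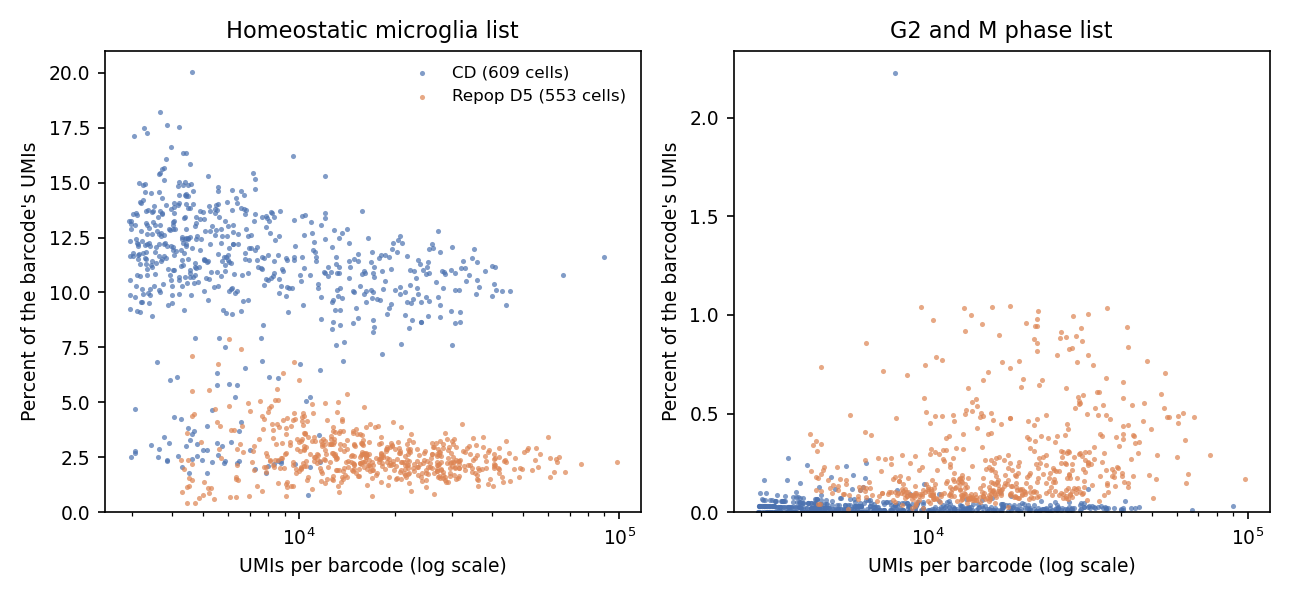
Each point is a retained cell of the CD (609 cells) or Repop D5 (553 cells) library, placed by its UMIs (horizontal, log scale) and by the percent of them from the homeostatic microglia list (left) or the G2 and M phase list (right). The median homeostatic share is 11.3% in CD and 2.41% in Repop D5, and the median G2 and M phase share 0.0208% and 0.175%. Most UMIs of the homeostatic list in the summed CD library are from Cst3, so the left panel leans on that gene.

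The cell cycle genes were higher as a group. Of 35 G2 and M phase genes, 35 were higher, with a median log2 ratio of 3.86 (3.73 to 4.17, percentile 100). Hmgb2, a chromatin protein and the most abundant member, had 121 CPM in CD and 618 CPM in Repop D5, and Bub1, a checkpoint kinase, 0.165 and 15.3 CPM. These had 74.8 and 630 CPM, and 0.316 and 16.3 CPM, outside clusters 4, 6 and 9. Of 27 S phase genes, 26 were higher, with a median of 2.98 (2.68 to 3.11, percentile 100). Pcna, the sliding clamp of DNA replication, had 56.1 and 158 CPM, and Slbp, which was neither, 87.2 and 111 CPM.

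A Mki67 UMI was found, after thinning each cell to 3000 UMIs, in 2 of 599 CD cells (0.334%, 0.0405 to 1.2) and 134 of 553 Repop D5 cells (24.2%, 20.7 to 28.0). Thinning left out 10 CD cells and 0 Repop D5 cells. Before thinning the shares were 0.985% and 62.9%. In neutrophil-like cells, taken as a type that does not divide, the thinned share was 1 of 41 in CD (median 6387 UMIs) and 0 of 7 in Repop D5 (median 5416 UMIs), the latter allowing up to 42.9%, so the background in Repop D5 is not known from them. They are no clean background in CD either. Before thinning, 2 of 42 of them held 2 or more Mki67 UMIs, as did 2 of 609 CD cells in all. Outside clusters 4, 6 and 9 the thinned shares were 0.238% and 25.5%. A looser measure, a UMI in 2 or more G2 and M phase genes, gave 12.7% and 89.0%, and 9.50% and 89.4% outside those clusters. The neutrophil-like cells gave 39.0% in CD and 7 of 7 in Repop D5, above the CD cells outside those clusters, so they give no background for this measure and no cycling is read from it.

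The disease-associated microglia list, genes known to be higher in microglia near plaques, went both ways. Of its 23 measured members 9 were higher and 11 lower, with a median log2 ratio of -0.27 (-0.29 to -0.24, percentile 21.8), which the trimmed-mean scaling turned to 0.19. Beside Spp1, Ch25h had 2.15 CPM in CD and 73.6 CPM in Repop D5, and Fth1, the ferritin heavy chain, 3291 and 6742 CPM. Apoe, the lipid carrier, had 7047 and 1094 CPM (2876 and 761 CPM outside clusters 4, 6 and 9), Cd63 had 633 and 135 CPM, and Ctsd, a lysosomal protease, 8517 and 3807 CPM. Lgals3, which encodes galectin-3, had 74.8 and 76.9 CPM (ratio 1.03, 0.916 to 1.16) in every retained cell and was 2.56-fold higher (1.97 to 3.37) outside clusters 4, 6 and 9.

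Type I interferon response genes were higher in part. Of 22 measured members 8 were higher, 1 lower and 13 neither, with a median of 0.34 (0.27 to 0.48, percentile 99.9), and outside clusters 4, 6 and 9 the median was 0.71 with 12 of 21 higher. Ifi27l2a had 165 CPM in CD and 1410 CPM in Repop D5, Cxcl10, a chemokine, 10.7 and 84.5 CPM, and Ifitm3 242 and 408 CPM. Ifi27l2a was 22.5-fold and Ifitm3 3.99-fold higher outside those clusters. Stat2, a signalling factor of the interferon receptor, had 16.7 and 10.2 CPM. MHC class II genes, which present antigen, were lower: 7 of 9 were lower and 1 higher, with a median of -1.58 (-1.92 to -1.41, percentile 0.03), and outside clusters 4, 6 and 9 the median was -0.86. Cd74, the invariant chain, had 1389 and 307 CPM and H2-Aa 493 and 71.7 CPM, against 247 and 175 CPM and 99.8 and 35.7 CPM outside those clusters. MHC class I genes had 0 higher and 3 lower of 12, with a median of -0.24 (-0.31 to -0.19, percentile 45.3) that turned to 0.21 with the trimmed-mean scaling and 0.02 without mt- and ribosomal protein genes.

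Energy and growth genes were higher. Glycolysis had 10 higher and 2 lower of 16 (median 1.40, percentile 100), with Eno1, enolase, at 179 CPM in CD and 746 CPM in Repop D5, Pkm, pyruvate kinase, at 232 and 796 CPM, and Hk2, hexokinase 2, lower at 520 and 205 CPM. Gapdh had 396 and 2560 CPM, with the reservation that many near-identical copies of this gene make its count uncertain. Nuclear-encoded oxidative phosphorylation had 32 higher and 0 lower of 36 (median 0.92, percentile 100.0), and the mitochondrially encoded genes 12 higher and 0 lower of 13 (median 0.99, percentile 98.0). The 32 Repop D5 barcodes left out by the cell filter held more mt- RNA by definition and are not in these values. Cholesterol synthesis had 19 higher and 0 lower of 20 (median 1.55, percentile 100), with Sqle, squalene epoxidase, at 2.48 and 62.0 CPM (40.9-fold higher outside clusters 4, 6 and 9) and Fdps at 22.1 and 234 CPM. Nucleolar and MYC target genes had 16 higher and 0 lower of 20 (median 0.97, percentile 100), with Ran at 171 and 811 CPM and Npm1, nucleophosmin, at 258 and 809 CPM. Actin and migration genes had 18 higher and 0 lower of 23 (median 1.2, percentile 100), with Tmsb4x, an actin-binding peptide gene, at 12917 and 44413 CPM and Capg at 41.6 and 768 CPM.

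**Figure D4:**
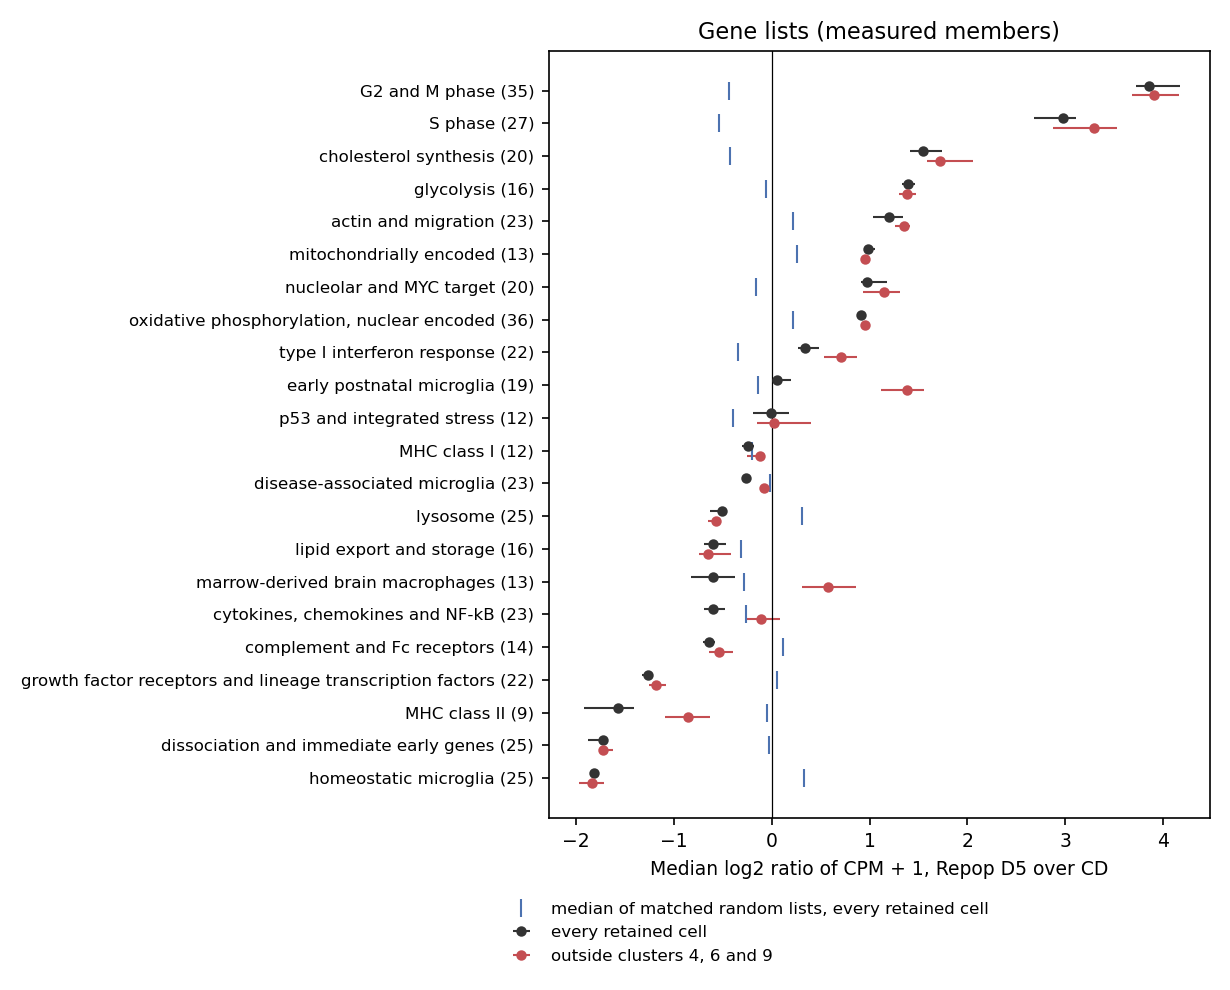
Median log2 ratio (Repop D5 over CD, horizontal) of each fixed gene list with its number of measured genes (vertical), for every retained cell and for cells outside clusters 4, 6 and 9, with 95% intervals from Poisson redraws of the counts, beside the median of random lists matched on expression. The G2 and M phase list lies at 3.86 and the homeostatic microglia list at -1.82, and the marrow-derived and early postnatal lists move most between the 2 sets of cells.

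Immediate early and dissociation genes, which handling of tissue can raise, were lower: 22 of 25 were lower and 1 higher, with a median of -1.73 (-1.88 to -1.69, percentile 0). Jun had 1835 CPM in CD and 236 CPM in Repop D5 and Klf4 110 and 12.8 CPM, while Hsp90aa1, a heat shock protein, was higher at 313 and 518 CPM. The growth factor receptor and lineage transcription factor list had 16 lower and 1 higher of 22 (median -1.27, percentile 0). Sall1, the transcription factor that sets microglial identity, had 299 and 52.7 CPM, and Csf2ra, a receptor chain for the growth factor GM-CSF, was higher at 98.1 and 195 CPM. Lysosome genes had 12 lower and 2 higher of 25 (median -0.51, percentile 0.74), with Ctsl at 972 and 250 CPM and Gusb at 204 and 517 CPM. Complement and Fc receptor genes had 7 lower and 3 higher of 14 (median -0.64, percentile 3.42), with C1qa at 9099 and 4447 CPM and Cfp, properdin, at 19.0 and 159 CPM. Lipid export and storage had 8 lower and 4 higher of 16 (median -0.60, percentile 13.3), with Abcg1, a cholesterol exporter, at 85.0 and 14.0 CPM and Cd36, a fatty acid scavenger receptor, at 20.8 and 236 CPM. Cytokine, chemokine and NF-kB genes had 12 lower and 6 higher of 23 (median -0.60, percentile 9.49). Outside clusters 4, 6 and 9, 7 were lower and 6 higher of 23, with a median of -0.11 (-0.26 to 0.08, percentile 76.7). In every retained cell, Ccl7 had 313 and 30.5 CPM and Ccl12 278 and 970 CPM. With the trimmed-mean scaling, the medians of these 4 lists lay between -0.19 and -0.05. Among the genes just named, the CPM outside clusters 4, 6 and 9 were 54.0 and 10.4 for Klf4, 4.42 and 158 for Cfp, 6.00 and 242 for Cd36, 57.8 and 26.8 for Ccl7, and 170 and 1010 for Ccl12.

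Where refilling microglia come from is a question this depletion model is used to address, and the remaining lists hold genes of other candidate origins. Neural stem and progenitor genes were mostly below 10 CPM: 3 of 16 were measured, with Nes and Vim (33.4 and 460 CPM) higher and Slc1a3 lower, and a median of 3.75 (percentile 100.0) that became 4.64 outside clusters 4, 6 and 9 and -0.30 with no minimum on the members. Vim is expressed by many cell types, and Nes was found by UMI after thinning in 0.668% of CD cells (0.182 to 1.70) and 16.6% of Repop D5 cells (13.6 to 20.0), against 2.63% and 58.0% before. The neutrophil-like cells gave a Nes UMI in 0 of 41 CD cells, which allows 7.32%, and 0 of 7 Repop D5 cells, which allows 42.9%. Of the marrow-derived brain macrophage list, 7 of 13 were lower and 4 higher (median -0.60, percentile 15.7), while outside clusters 4, 6 and 9 the median was 0.57 with 6 of 12 higher. Ccr2, the chemokine receptor of monocytes, was 1.53-fold lower (1.29 to 1.83) in every retained cell and 2.45-fold higher (1.52 to 4.19) outside those clusters. The latter rests on 19 CD and 152 Repop D5 counts. The summed monocyte markers, Ccr2 among them, moved the same way, from 274 and 258 CPM in every retained cell to 53.7 and 149 CPM outside those clusters, 2.78-fold higher (2.37 to 3.28). Cluster 6 was named from these same markers, so leaving it out takes away the cells richest in them. No origin is read from the values that remain. Mrc1, a mannose receptor of border macrophages, had 184 and 12.7 CPM in every retained cell. It had 393 CPM in cluster 4, which held CD cells only and of which it is a leading gene. The early postnatal microglia list had 9 higher and 8 lower of 19 (median 0.06, percentile 72) and a median of 1.39 outside clusters 4, 6 and 9, with Lpl, lipoprotein lipase, at 16.7 and 161 CPM and Pf4 at 429 and 56.3 CPM (134 and 39.0 CPM outside them). Of the haematopoietic stem and progenitor list 2 genes were measured, Cd34 (104 and 314 CPM) and Ly6a (22.3 and 6.61 CPM), with a median of -0.02 (percentile 56.5). That median was -0.50 outside clusters 4, 6 and 9, with Ly6a at 17.7 and 2.71 CPM.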

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

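No paired analysis was possible because each group is 1 pooled library. The direction of the homeostatic, G2 and M phase and interferon lists was the same under each alternative run, while the balance of higher and lower genes and the disease-associated list turned with the scaling. Summing every retained cell, listed in advance as an alternative, is the main value here, since the microglia-like class failed its check, and has no value of its own. Of 163 named genes, 10 turned direction under at least 1 alternative, and of 26 lists, 4 did; the cause was not tested. A gene or list was counted only if its own interval lay clear of a log2 ratio of 0, which leaves out the p53 list (0.020 outside clusters 4, 6 and 9) and the haematopoietic list (0.41 with trimmed-mean scaling), whose signs also changed. Depth limits the CD values of cell cycle genes, many of which rest on under 10 counts. Summing the cells outside clusters 4, 6 and 9 was chosen after the data were seen.

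The genes at least 2-fold higher in the Repop D5 library numbered 981 with trimmed-mean scaling, 701 without mt- and ribosomal protein genes, 813 at 10 CPM and 1186 with no minimum. The genes at least 2-fold lower in the Repop D5 library numbered 349 with trimmed-mean scaling, 2015 at 10 CPM and 3465 with no minimum, the last pairs because more genes were counted. The 431 higher genes were all among the 981, which follows from the scaling, since it raises every ratio by the same factor. The homeostatic median was -1.96 with the stricter cell filter, -1.73 without the cells of most UMIs, -1.72 thinned, -1.37 with trimmed-mean scaling, -1.56 without mt- and ribosomal protein genes, -1.65 with equal weight per cell, -1.77 at 50 CPM and -1.62 with a pseudocount of 10 CPM. For G2 and M phase it was 3.65 thinned, 4.30 with trimmed-mean scaling, 4.23 without mt- and ribosomal protein genes, 3.49 with equal weight, 4.29 at 50 CPM and 2.13 with the larger pseudocount. For the disease-associated microglia list, median log2 ratios were -0.30 with the stricter filter, -0.080 outside clusters 4, 6 and 9, 0.19 with trimmed-mean scaling, -0.0021 without mt- and ribosomal protein genes and -0.23 with equal weight. For the interferon list it was 0.71 outside clusters 4, 6 and 9, 0.53 thinned, 0.88 with trimmed-mean scaling, 0.69 without mt- and ribosomal protein genes and 0.50 with equal weight.

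The share of retained cells called microglia-like, CD first, was 74.3% with the stricter filter, 64.2% and 81.0% at Leiden resolutions 0.5 and 2, 79.8% with 15 components, 82.0% without called doublets and 74.9% in the pooled matrix. The share of retained cells called microglia-like, Repop D5 next, was 96.2% with the stricter filter, 96.4% at resolution 0.5, 96.6% with 15 components and 98.4% in the pooled matrix. In these runs the monocyte-like cluster was kept, unnamed or absent, and an endothelial-like cluster appeared in several. A border macrophage-like cluster was named in each, but its share was not taken. Where the CD microglia-like share rose, as to 82.0%, all other classes together held fewer CD cells. The border macrophage-like share of 17.7% is thus that of the main clustering alone. The Repop D5 Mki67 share was 62.9% unthinned, 41.2% for 2 or more UMIs and 89.0% for 2 or more G2 and M phase genes, which gave 12.7% in CD.

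With trimmed-mean scaling the log2 values of MHC class I (0.21), Bin1 (0.31), H2-D1 (0.15), B2m (0.28), Npc2 (0.17), Itga6 (0.13) and Capza2 (0.34) turned. Without mt- and ribosomal protein genes those of MHC class I (0.019), Bin1 (0.11), B2m (0.084) and Capza2 (0.14) did. Outside clusters 4, 6 and 9 the marrow-derived list (0.57), Ccr2 (1.17), Olfml3 (-0.071) and Cd9 (-0.14) turned. Thinning turned Nsdhl (-0.32) and Cd9 (-0.10), equal weight turned Cd9, log2 ratio -0.066, and no minimum on members turned the neural stem and progenitor list (-0.30).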

Other observations

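The pooled libraries also differed in lists outside the main comparison. Sex-linked genes had 3 lower and 0 higher of 4 measured, all Y-linked, with a median log2 ratio of -0.68 (percentile 24.1) and Ddx3y at 107 CPM in CD and 41.0 CPM in Repop D5. The p53 and integrated stress list went both ways, with 5 higher and 4 lower of 12 (median -0.01, percentile 89.0). In it Cdkn1a, the gene of the cell cycle inhibitor p21, had 35.3 and 147 CPM and Sesn1 80.1 and 27.2 CPM. Haemoglobin genes were lower (median -7.95), a value that 1 CD barcode sets: it held 9569 of the 9917 haemoglobin UMIs of that library, and outside clusters 4, 6 and 9 the median was -8.95; the copies Hba-a1 and Hba-a2 are so alike that their own counts are uncertain.

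Markers of other cell types were found in both libraries. Monocyte markers outside clusters 4, 6 and 9 came to 53.7 CPM in CD and 149 CPM in Repop D5. Neutrophil markers there came to 2346 CPM in CD and 836 CPM in Repop D5, and S100a8, an abundant neutrophil gene, had a UMI after thinning in 96.2% of CD cells and 57.7% of Repop D5 cells (99.2% and 95.8% before). Astrocyte markers were at 182 CPM in CD and 12.2 CPM in Repop D5, of which Slc1a3, also a leading gene of the microglia-like cluster 1, made 167 and 4.26 CPM. B cell markers were at 40.1 and 3.44 CPM. Oligodendrocyte markers were at 91.3 and 73.2 CPM. Oligodendrocyte precursor markers were at 1.98 and 14.0 CPM, of which Cspg4 had 0 UMIs in CD and 128 UMIs in Repop D5.

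Patterns weighed here are the higher UMI count of Repop D5 barcodes, the mixed RNA of cluster 4 and the lower homeostatic genes. All their tests were chosen after the result was seen, except the doublet test of the first pattern and the test by thinning of the third; that the doublet test decides nothing was also judged after its value was seen.

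Repop D5 barcodes held more UMIs. Deeper sequencing alone is argued against by the stated reads per cell, which differ by a factor of 1.04. In the pooled matrix the ratio of medians was 2.55. That adds little, since this matrix kept 100% of the CD and 96.8% of the Repop D5 UMIs. More cycling cells could account for part, since in barcodes without a UMI of 7 cell cycle genes (22 in Repop D5, 414 in CD) the ratio was 1.46. That test is undecided, because such barcodes are also those with few UMIs, and a first choice that left 3 Repop D5 barcodes gave 1.84. Several cells under 1 barcode stay open too: without the called doublets the ratio was 2.72, but only 5 and 8 barcodes were called, removing the 8 highest of Repop D5 would still give 2.70, and pairs of like cells are hard to call.

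Cluster 4 of the CD library carried border macrophage and microglial RNA together. Free RNA of microglia stays open: the median microglia marker CPM of its barcodes was 3.26 times (1.18 to 5.02, barcodes redrawn) that of the CD barcodes of cluster 9, where 22 of 42 lay under 50% of the cluster 4 median, but the ratio of the sums was 1.28. Those 22 had a median of 4890 UMIs and the other CD barcodes of cluster 9 a median of 19957 UMIs. The sums thus weigh the latter more, and whether these hold several cells was not tested. Several cells under 1 barcode is a candidate explanation for cluster 4. Its median UMIs were 3.41 times those of the CD microglia-like clusters and its microglia markers 0.869 times theirs, although Scrublet called only 4 of the 108. Few doublets were expected in advance at the number of barcodes per library, while cluster 4 held 17.7% of CD cells. Free RNA of border macrophages, whose markers were 4.35 times those of the other barcodes, stays open, in part because those genes define the cluster. A biological explanation, cells that express both sets of genes, was not tested.

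Homeostatic genes were lower in Repop D5. A different mix of other cell types is argued against by the median of -1.84 outside clusters 4, 6 and 9. Cycling cells stay open. In 22 Repop D5 and 414 CD barcodes there without a UMI of 7 cell cycle genes, the median was -1.58 (-1.72 to -1.29). It was -1.66 with the other clusters kept. Such barcodes are also those with few UMIs (median 7147 in Repop D5), so lacking these UMIs does not show that a cell is not cycling. The UMI count per barcode is argued against by the median of -1.78 (-1.84 to -1.63) in barcodes of 7980 to 14840 UMIs. These were 163 Repop D5 and 68 CD barcodes outside clusters 4, 6 and 9. Thinning, the test fixed first, gave -1.72 but hardly moves a ratio of CPM by its construction. A difference between preparations cannot be told apart from the treatment with 1 library per group, and neither can a difference between the pools of mice. The design's own difference, depletion and refilling, stays open as untested.

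Nes was higher in the Repop D5 library, and a hypothesis is that it goes with the cell cycle. Its CPM in Repop D5 barcodes with 2 or more G2 and M phase genes was 2.39 times (1.02 to 7.40) that in those with none, but only 11 barcodes had none and, as in the main comparison, no cycling is read from that measure, so this does not decide it. Nes and Mki67 were at 76.4 and 257 CPM in cluster 3, 75 and 109 CPM in cluster 5, 48.3 and 85.9 CPM in cluster 10, 39.9 and 72.5 CPM in cluster 11 and 25.7 and 31.4 CPM in cluster 7, so they fell in the same order, though by unlike factors. Cluster 2, with 90 and 40.9 CPM, departs from that order and goes against the hypothesis, but Nes is among its leading genes. Clusters 3 and 5 are in the same way led by genes of division and DNA synthesis. Median UMIs were also higher in clusters 3 and 5 (22215 and 26060) than in clusters 10, 11 and 7 (17297, 12359 and 9584). The levels by cluster therefore do not decide it, and the hypothesis stays open.

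RNA of other cells could also bring Nes: its level outside clusters 4, 6 and 9 was 2.31 times (1.51 to 3.71) that in clusters 6 and 9, between the bounds set for either answer. Neural progenitors and endothelial cells as its source are argued against: their other markers were at 0.126 (0.0650 to 0.228) and 0.503 (0.440 to 0.576) times the CD level, and at 0.0741 (0.0382 to 0.134) and 0.317 (0.245 to 0.410) times outside those clusters, with 1.27 and 38.1 CPM in the Repop D5 library beside Nes at 68.5 CPM. Pericytes stay open, with 0.341 (0.178 to 0.634) times in every retained cell but 0.701 (0.273 to 2.02) outside those clusters, although their markers came to only 1.63 CPM. Oligodendrocyte precursors stay open too: their markers were 7.09-fold higher (3.94 to 14.0), but Cspg4 held 128 of the 155 UMIs, and the others were at 1.98 and 2.45 CPM, a ratio of 1.23 (0.605 to 2.67). The test by these markers was chosen after the levels were seen. The tests of Nes by G2 and M phase genes and by clusters 6 and 9 were chosen before their results were seen. They use sets of cells that were chosen after the clusters were seen. The levels of Nes and Mki67 by cluster were not a test set in advance.

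A further hypothesis, chosen after, is that homeostatic genes are lower in cycling cells within Repop D5. The median log2 ratio between barcodes with 2 or more G2 and M phase genes and those with none was -0.15 (-0.29 to -0.06), which does not decide it either, with 11 barcodes in the latter set and a measure from which no cycling is read.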
